A study of Homo sapiens with 22 samples.

How the data were processed

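RNA-seq counts were analysed for 10 libraries of the colorectal carcinoma line HCT116: parental cells (WT), MLL4 knockout cells with an uninduced TET-ON cassette, and the same cells after 2, 4 and 8 days of doxycycline, 2 libraries each. Per the labels, the RNA was poly(A) RNA, cells grew in DMEM with 10% serum, doxycycline induced GFP-MLL4-HMG-USD, and WT cells were not treated. The series also holds 12 chromatin immunoprecipitation samples (input, UTX, H3K27me3 and GFP), which were not analysed here.

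The authors' deposited table holds raw read counts per Ensembl gene, with 16598 genes and 1 column per library; the values were checked to be whole numbers. The smallest total of a gene over the 10 libraries was 61, so genes with lower totals had been left out before. The authors' notes name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 0.12.9, MACS2 2.1.0, MACS 1.4.2 and HTSeq with the human build hg19, without saying which served the RNA libraries. The RNA aligner, the gene annotation and the strand of the libraries are not given in the sources used here. A gene symbol was found for 16026 identifiers and not for 572. KMT2B had no count under its symbol and was not analysed here.

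In M (mega) counts, library totals ran from 5.19 M (WT replicate 2) to 54.4 M counts, and from 22.9 M without that library. A gene at 0 counts in a group was given a floor of 3 counts over the group and its fold change as a lower bound. A gene with 1 to 3 counts was given the ratio with an exact 95% counting interval. PCR copies are not independent molecules, so intervals and floors cover counting error only.

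Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which removed 12 and left 16586. Libraries were scaled by TMM, and 1 mean per group was fitted over all 10 libraries with the robust quasi-likelihood test, leaving 5 residual degrees of freedom. The 6 contrasts were knockout against WT, each day against uninduced, day 8 against day 2, and day 8 against WT; a joint test covered the 3 days. P-values were adjusted by Benjamini-Hochberg over all genes, and a gene was called at an adjusted p below 0.05. The standard error of a log2 fold change follows from the test statistic. Abundances are counts per M counts (CPM) after TMM scaling. No replicate term was used, since the labels do not say that equal numbers share a batch.

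A total of 36 gene lists were fixed: MLL3-4 and COMPASS subunits, Polycomb PRC2, Polycomb PRC1, HOX genes, other developmental Polycomb targets, retinoic acid targets, enterocyte, secretory lineage, Wnt and intestinal stem cell, epithelial adhesion and keratin, mesenchymal, collagen and matrix, TGF-beta and BMP targets, ERK pathway targets, AP-1 and immediate early, YAP and TEAD targets, p53 targets, cell cycle G1/S, cell cycle G2/M, cholesterol synthesis, lipid synthesis, hypoxia and glycolysis, integrated stress response, unfolded protein response, mitochondrial DNA genes, nuclear respiratory chain, mitochondrial ribosome, NRF2 and oxidative stress, interferon-stimulated, antigen presentation, NF-kB and cytokine, histone genes, cytosolic ribosomal proteins, and markers of fibroblasts, of blood and endothelium, and of neural and kidney lines. Some genes stand in more than 1 list, such as TGFB2, DDIT4 and GDF15. Lists with at least 5 tested genes (34 of 36) were tested with camera in limma 3.58.1 at a preset correlation of 0.01 in 4 contrasts, adjusted over all 136 tests, and again with the correlation estimated. Calls were also counted with p-values adjusted over the list alone.

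Genes were named by a rule: KMT2D, KMT2C, KMT2B and KDM6A always; for the knockout the 12 genes with the largest fold change up and the 12 down among called genes with a mean of at least 5 CPM in the higher group and libraries that did not overlap; 8 and 8 for each day and for all days together; 6 and 6 for genes moved toward WT at day 8; and up to 4 called genes per list with at least 1 CPM. Clone-based and pseudogene names were left out of the ranked sets. Some list examples are not reported here. The lists, the naming rule, the contrasts, the tests and most alternatives were chosen before the data were examined.

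Movement toward WT was counted as genes called in the knockout and called the other way with doxycycline. It shares the uninduced libraries between both contrasts, so 20 data sets were simulated in which all groups had the uninduced mean and each group its own spread. After the data were seen, 20 more were simulated in which WT kept its own mean. In addition, the covariance was computed with a different uninduced library on each side. The procedure was tested on simulated data with 200 genes changed by 1.5-fold, 2-fold or 4-fold.

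Alternatives were DESeq2 size factors, total counts as the only scaling, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, replicate number as a block, only the libraries compared, a minimum absolute log2 fold change of 1, and each library left out in turn, where the lone library of a group is assumed to vary like the others. For lists, fry replaced camera. Added after the data were seen were limma voom with a weight per group, a crossed block on the uninduced and day 8 libraries, and camera on day 8 against day 2.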

Results

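RNA abundance was measured in HCT116, a line of colorectal carcinoma cells, in 10 poly(A) RNA libraries that form 5 groups of 2. The groups were parental cells (WT), cells with a knockout of MLL4 and an inducible cassette that was left uninduced, and the same knockout cells after 2, 4 and 8 days of doxycycline. MLL4 is the product of KMT2D, a histone methyltransferase that marks enhancers and works in a complex with the demethylase UTX (KDM6A). Doxycycline switches on GFP-MLL4-HMG-USD, a tagged small domain of MLL4. Library totals were 37.1 and 5.19 M (mega) counts in WT, 22.9 and 38.1 M in uninduced cells, 43.9 and 43.2 M at day 2, 36.3 and 37.3 M at day 4, and 32.3 and 54.4 M at day 8. No WT cells were given doxycycline, so an effect of the drug itself was not separated from that of the domain. The sources used here do not state whether replicates came from separate cultures, so every p-value measures only the spread between these samples, which could be technical. Values are counts per M counts (CPM) as mean ± SD of n = 2 libraries and log2 fold changes with their standard error (SE).

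KMT2D (ENSG00000167548) stood at 149 and 152 CPM in the 2 WT libraries and at 10 and 6.34 CPM in the uninduced knockout libraries. With doxycycline it was 36 and 35.2 CPM at day 2, 35.4 and 35.2 CPM at day 4, and 29 and 30.2 CPM at day 8. The uninduced mean of 8.19 ± 2.62 CPM was 5.45% of the WT mean (log2 fold change -4.23, SE 0.16, adjusted p = 3.6e-09). Induced means were 23.7%, 23.5% and 19.7% of WT, and KMT2D rose on all 3 days against uninduced cells (2.15, 2.14 and 1.88; adjusted p = 1.6e-05, 2.6e-05 and 2.6e-05). Counts per gene do not tell reads of the induced domain from reads of the endogenous gene. The paralog KMT2C (ENSG00000055609, MLL3) was 41.8 ± 4.15 CPM in WT and rose to 72.2 ± 18 CPM in uninduced cells (0.81, SE 0.15, adjusted p = 0.00059). At day 2 it was 56 ± 1.26 CPM (-0.36, adjusted p = 0.11) and at day 8 it was 60.4 ± 6.54 CPM (-0.25, adjusted p = 0.22). The 2 uninduced libraries differed, at 85 and 59.5 CPM. Without uninduced replicate 2 the log2 fold change of KMT2C was -0.6 at day 2 and -0.49 at day 8. Without uninduced replicate 1 it was 0.03 at day 8, so the KMT2C change depends on the uninduced library used. KDM6A (ENSG00000147050) was 20.5 ± 2.14 CPM in WT and 29 ± 1.56 CPM in uninduced cells (0.46, SE 0.14, adjusted p = 0.012), a call that ended without WT replicate 2 (0.4, adjusted p = 0.066). With doxycycline KDM6A was 28.8 ± 1.15, 30.6 ± 3.17 and 28.5 ± 5.09 CPM, and no day passed the test (adjusted p = 0.98, 0.76 and 0.94).

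**Figure D1:**
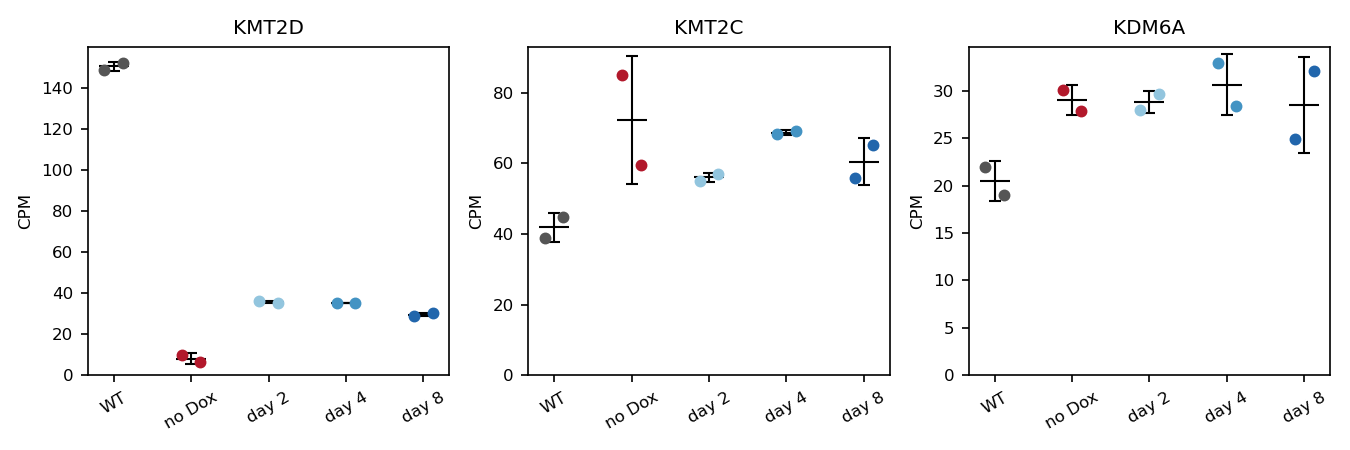
Abundance (CPM, 1 point per library, bar and whisker for mean ± SD of 2) of KMT2D, KMT2C and KDM6A in the 5 groups. KMT2D lay at 149 and 152 CPM in WT, at 10 and 6.34 CPM in uninduced knockout cells, and between 29 and 36 CPM in the 6 induced libraries.

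The comparison of uninduced knockout cells with WT asks what differs between the knockout line and its parental cells. The knockout cells also carry the cassette. Effects of the cassette, of making the line or of separate culture cannot be told apart here from loss of MLL4. Epithelial genes were among the most reduced. KRT7, a keratin, was 0.464 ± 0.185 CPM against 32.6 ± 3.16 CPM in WT (66.7-fold lower, log2 SE 0.25, adjusted p = 6.1e-09), and ELF3, an epithelial transcription factor, was 1.34 ± 0.00892 against 85.2 ± 0.567 CPM (63.3-fold lower, SE 0.2, adjusted p = 1.4e-09). HAS3, a hyaluronan synthase, was 15.2-fold lower (25.3 ± 0.0685 against 384 ± 6.73 CPM, SE 0.09, adjusted p = 8.1e-11). The sodium channel subunit SCNN1A was 28.5-fold lower, and the calcium-binding S100A4 and S100A14 were 12.5-fold and 11.5-fold lower. KLK6 (61.3-fold), KRT80 (34.9-fold), IRAG1 (18.9-fold), CYP4F11 (18.4-fold; log2 -4.2, and -4.9 without uninduced replicate 2) and the imprinted RNA H19 (13.9-fold) complete the 12 genes with the strongest decrease, KMT2D among them.

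Ligands and targets of TGF-beta signalling were among the genes with the strongest increase in the knockout. INHBA, which encodes a subunit of activin, had 0 counts in both WT libraries and 35.6 ± 3.92 CPM in uninduced cells, at least 445-fold higher against a floor of 3 counts over the WT group. TGFB2, a TGF-beta ligand, was 28.4 ± 3.93 against 0.715 ± 0.428 CPM (30.3-fold, SE 0.22, adjusted p = 1e-08), and PMEPA1, a TGF-beta target, was 12 ± 0.708 against 0.459 ± 0.226 CPM (34.7-fold, SE 0.27, adjusted p = 3.2e-08). SCN9A, a sodium channel, and EPHA7, an ephrin receptor, also had 0 WT counts and were at least 70.6-fold and 68.2-fold higher. CAVIN2, a caveolar coat protein, rested on 1 WT count, with a ratio of 597 (95% counting interval 107 to 23600). LRP1B (237-fold), TMEM132B (45.4-fold), GLIPR1 (33.6-fold), RCAN2 (33.6-fold), CRACDL (30.2-fold) and the chromatin organiser SATB1 (28.2-fold) make up the rest of the 12. All of these genes passed the test without any one of the 4 libraries. Their size rests on few WT counts. Without WT replicate 1 the log2 fold changes were 6.09 for TGFB2, 4.27 for PMEPA1, 4.37 for GLIPR1 and 4.22 for SATB1, against 4.92, 5.12, 5.07 and 4.82 with all libraries. LRP1B and RCAN2 had 0 counts in WT replicate 2. Without WT replicate 1 (13.14 and 11.66) their size therefore has no upper bound. With voom, RCAN2 was 5.72.

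Cell cycle genes fell together in the knockout. All 36 tested genes of the G1/S list and 35 of 36 in the G2/M list were lower (36 and 35 adjusted over the list alone), with medians of -1.27 and -1.03. RRM2, which makes DNA precursors, was 212 ± 10.1 against 696 ± 14.7 CPM (3.29-fold lower), CCNA2, a cyclin, was 52 ± 3.65 against 191 ± 7.06 CPM (3.69-fold lower), and the replication helicase subunit MCM5 was 2.93-fold lower. Camera gave adjusted p = 1.1e-32 for G1/S and 1.7e-20 for G2/M, and adjusted p = 0.11 for each with an estimated correlation. The mitochondrial ribosome list moved the same way, with 38 of 40 genes lower and 0 higher (39 lower adjusted over the list alone), led by MRPS2 at 2.72-fold (median -0.74, adjusted p = 3.8e-11, and adjusted p = 0.4 with an estimated correlation). Of the 45 nuclear genes of the respiratory chain, 30 were lower and 0 higher (30 adjusted over the list alone; median -0.37, adjusted p = 0.0041, and adjusted p = 0.79 with an estimated correlation). That list's call ended without uninduced replicate 1 (-0.25, adjusted p = 0.064). The p53 target list rose, with 18 of 32 higher and 5 lower (18 and 5 adjusted over the list alone), among them GDF15, a stress cytokine (7.32-fold), and TP53INP1 (7.05-fold), with a median of 0.48 (adjusted p = 7.4e-05, and adjusted p = 0.33 with an estimated correlation).

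TGF-beta and BMP targets rose, with 15 of 19 genes higher and 1 lower (15 and 1 adjusted over the list alone) and a median of 1.93, also with INHBA at its bound (adjusted p = 1.5e-11, and adjusted p = 0.11 with an estimated correlation). SMAD7, a feedback inhibitor of the pathway, was 9.59-fold higher (log2 3.26, and 4.28 without WT replicate 1). Collagen and matrix genes rose too, with 18 of 25 higher and 4 lower (18 and 4 adjusted over the list alone), such as the laminin LAMB1 (3.76-fold) and the perlecan gene HSPG2 (2.79-fold), with a median of 0.64 (adjusted p = 0.0029, and adjusted p = 0.4 with an estimated correlation). Epithelial adhesion and keratin genes fell, with 21 of 33 lower and 4 higher (21 and 4 adjusted over the list alone), among them the tight junction claudin CLDN4 (6.05-fold lower), with a median of -0.46 (adjusted p = 6.1e-08, and adjusted p = 0.075 with an estimated correlation). Mesenchymal genes went both ways: 10 of 17 were higher, such as VIM, an intermediate filament (4.89-fold), and 3 were lower, such as the receptor kinase AXL (6.32-fold), and the list did not pass (median 0.89, adjusted p = 0.31; 10 and 3 adjusted over the list alone). ERK pathway targets rose, with 13 of 23 higher and 7 lower (14 and 7 adjusted over the list alone). Their strongest increase was DUSP6, a phosphatase that restrains ERK, at 783 ± 43.5 against 48.7 ± 5.34 CPM (15.8-fold, adjusted p = 8.1e-11; list median 0.58, adjusted p = 0.0034, and adjusted p = 0.33 with an estimated correlation). AP-1 and immediate early genes rose, with 13 of 25 higher and 6 lower (13 and 7 adjusted over the list alone), among them JUN (7.23-fold) and EGR3 (9.1-fold; log2 3.19, and 2.51 without WT replicate 1), with a median of 0.32 (adjusted p = 0.0041, and adjusted p = 0.49 with an estimated correlation).

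Stress and immune lists also differed from WT. In the integrated stress response list 21 of 40 genes were higher and 10 lower (22 and 11 adjusted over the list alone; median 0.3, adjusted p = 0.001, and adjusted p = 0.44 with an estimated correlation). CHAC1, which degrades glutathione, was 6.57-fold higher in that list, and NUPR1 rested on 1 WT count with a ratio of 131 (95% counting interval 23.2 to 5190). Of the 23 antigen presentation genes, 19 were higher and 2 lower (19 and 2 adjusted over the list alone; median 1.12, adjusted p = 8.4e-05, and adjusted p = 0.4 with an estimated correlation). HLA-DRA, 9.09-fold higher (log2 3.18, and 2.31 without WT replicate 1), is an example, though class II genes resemble one another and reads may be assigned across them. Cholesterol synthesis genes fell, with 18 of 26 lower and 3 higher (18 and 3 adjusted over the list alone), such as the sterol enzyme ACAT2 (2.51-fold lower), against a 5.09-fold increase of TM7SF2 (median -0.48, adjusted p = 0.0067, and adjusted p = 0.41 with an estimated correlation). NRF2 and oxidative stress genes fell, with 17 of 23 lower and 5 higher (17 and 5 adjusted over the list alone), among them the ferritin light chain FTL (3-fold lower), with a median of -0.52 (adjusted p = 0.031, and adjusted p = 0.4 with an estimated correlation). That call ended without WT replicate 2 (-0.52, adjusted p = 0.055) or uninduced replicate 1 (-0.44, adjusted p = 0.052). Retinoic acid targets had a median of 0.24, a mean of -0.41 and a camera test that pointed down (adjusted p = 0.0041, and adjusted p = 0.44 with an estimated correlation). Of 10 genes, 2 were higher and 4 lower, also adjusted over the list alone; the lower ones included CRABP2, a retinoic acid binder (6.54-fold). With a voom weight per group the calls of the retinoic acid, ERK and AP-1 lists ended (adjusted p = 0.17, 0.058 and 0.059).

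Mitochondrial DNA genes were higher in the knockout in 8 of 13 cases and lower in 1 (8 and 1 adjusted over the list alone; median 0.64, adjusted p = 0.044, and adjusted p = 0.74 with an estimated correlation). MT-CO1, a cytochrome oxidase subunit, was 5660 ± 453 against 2080 ± 119 CPM (2.72-fold); nuclear copies of these genes resemble them. The list's call ended without WT replicate 2 (0.68, adjusted p = 0.14), uninduced replicate 1 (0.68, adjusted p = 0.062) or uninduced replicate 2 (0.59, adjusted p = 0.26). RNA composition moved with this group: mitochondrial rRNA took 2.8% and 1.27% of counts in the uninduced libraries against 0.762% and 0.738% in WT, and the nuclear RNAs MALAT1 and NEAT1 took 0.325% and 0.166% against 0.0479% and 0.0565%. Small noncoding RNAs, which poly(A) selection mostly removes, stood at 292 and 93.9 CPM in the uninduced libraries against 93.4 and 84.9 CPM in WT. For small noncoding RNA only uninduced replicate 1 stood apart. Other developmental Polycomb targets were higher in 19 of 38 cases and lower in 3 (19 and 3 adjusted over the list alone; median 0.43, adjusted p = 0.036, and adjusted p = 0.47 with an estimated correlation), led by CDKN2B, a cell cycle inhibitor, at 9.25-fold. That call ended without WT replicate 1 (0.39, adjusted p = 0.066) or uninduced replicate 2 (0.39, adjusted p = 0.073).

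**Figure D2:**
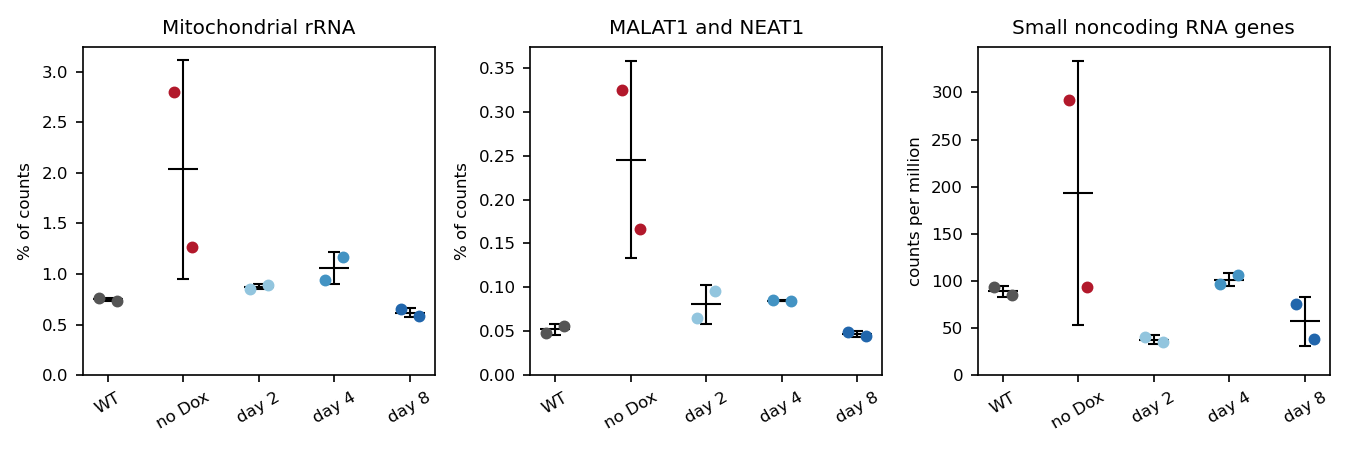
Share of counts from mitochondrial rRNA (%), share from MALAT1 and NEAT1 (%), and small noncoding RNA (CPM), 1 point per library in the 5 groups. Uninduced replicate 1 had the highest value of all 3 measures, with 2.8%, 0.325% and 292 CPM.

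The other lists did not pass the camera test in the knockout. Counts of genes higher and lower were 7 and 11 of 19 for MLL3-4 and COMPASS subunits (median -0.25, adjusted p = 0.16), 2 and 5 of 12 for Polycomb PRC2 (-0.11, adjusted p = 0.66) and 4 and 3 of 19 for Polycomb PRC1 (0.09, adjusted p = 0.69). Within them KDM6B, a demethylase of H3K27, rose 2.34-fold, JARID2, a PRC2 cofactor, rose 3.67-fold, and the PRC2 methyltransferase EZH2 fell (1.83-fold lower). HOX genes gave 11 and 8 of 27 (0.11, adjusted p = 0.72; 12 and 8 adjusted over the list alone), Wnt and intestinal stem cell genes 11 and 5 of 23 (0.48, adjusted p = 0.066), enterocyte genes 1 and 2 of 6 (-0.15, adjusted p = 0.6), and secretory lineage genes 2 and 0 of 7 (0.31, adjusted p = 0.71). RNF43, which restrains Wnt signalling, fell (7.16-fold lower). YAP and TEAD targets gave 5 and 9 of 21 (-0.2, adjusted p = 0.19), lipid synthesis genes 5 and 13 of 26 (-0.28, adjusted p = 0.13; 6 and 13 adjusted over the list alone), hypoxia and glycolysis genes 20 and 14 of 40 (0.38, adjusted p = 0.17; 21 and 14 adjusted over the list alone) and unfolded protein response genes 8 and 6 of 24 (0.13, adjusted p = 0.27). Interferon-stimulated genes gave 15 and 7 of 34 (0.46, adjusted p = 0.21), NF-kB and cytokine genes 9 and 4 of 21 (0.33, adjusted p = 0.93), histone genes 4 and 0 of 13 (median -0.1, mean 0.1 and test up, adjusted p = 0.63) and cytosolic ribosomal proteins 6 and 2 of 54 (0.03, adjusted p = 0.8; 1 and 0 adjusted over the list alone). Marker lists of other cells, some of which tumour lines also express, gave 3 and 0 of 4 for fibroblasts (median 1.58, or 1.46 with genes of 0 counts at their bound), 0 and 0 of 4 for blood and endothelium (0.09), and 3 and 2 of 6 for neural and kidney lines (0.43, adjusted p = 0.8). The first and second of these marker lists were too short for the camera test. Where no second count is given, the counts adjusted over the list alone were equal.

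In total 9482 of 16586 genes were called in the knockout against WT, 4895 higher and 4587 lower (edgeR, adjusted p below 0.05), and 2412 of the higher and 966 of the lower genes differed by at least 1 on the log2 scale. Without WT replicate 1, which leaves only the WT library of 5.19 M counts, 6259 genes were called. Scaled by total counts alone, the median of all genes shifted by 0.176 on the log2 scale and the calls split into 6327 higher and 3382 lower, so directions are relative to the TMM scaling used. Simulated changes of 1.5-fold, 2-fold and 4-fold were recovered in 37.3%, 70.1% and 87.9% of the genes so changed in this comparison. That simulation changed only 200 genes, against the 9482 called here. An adjusted p depends on how many genes change, so these rates need not hold for the real data.

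The comparisons of induced with uninduced knockout cells ask what the small MLL4 domain changes after 2, 4 and 8 days. CEMIP, a hyaluronan-degrading protein, rose from 6.64 ± 0.161 CPM to 23.3 ± 1.45, 41.7 ± 2.5 and 34.9 ± 1.23 CPM (3.51-fold, 6.29-fold and 5.27-fold, SE 0.12 each; adjusted p = 1.6e-05, 5.5e-07 and 8.8e-07), above the 3.503 and 5.156 CPM of the WT libraries. FOXM1, a transcription factor of dividing cells, rose from 69.8 ± 0.246 to 143 ± 0.785, 116 ± 0.0858 and 142 ± 12 CPM (1.03, 0.73 and 1.03), with 213 ± 4.43 CPM in WT. SAT1, a polyamine-degrading enzyme, fell from 454 ± 58.3 to 163 ± 0.0809, 198 ± 0.165 and 130 ± 16.2 CPM (-1.48, -1.2 and -1.81), with 137 ± 7.77 CPM in WT. DDIT4, a stress-induced inhibitor of mTORC1, fell from 147 ± 18.8 to 75 ± 0.212, 40.6 ± 2.84 and 42 ± 3.98 CPM (-0.98, -1.86 and -1.81), with 49.1 ± 8.7 CPM in WT. S100A14, already 11.5-fold lower in the knockout, fell further from 12.8 ± 0.8 to 3.87 ± 0.0467, 3.9 ± 0.653 and 1.91 ± 0.168 CPM (-1.73, -1.72 and -2.76).

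**Figure D3:**
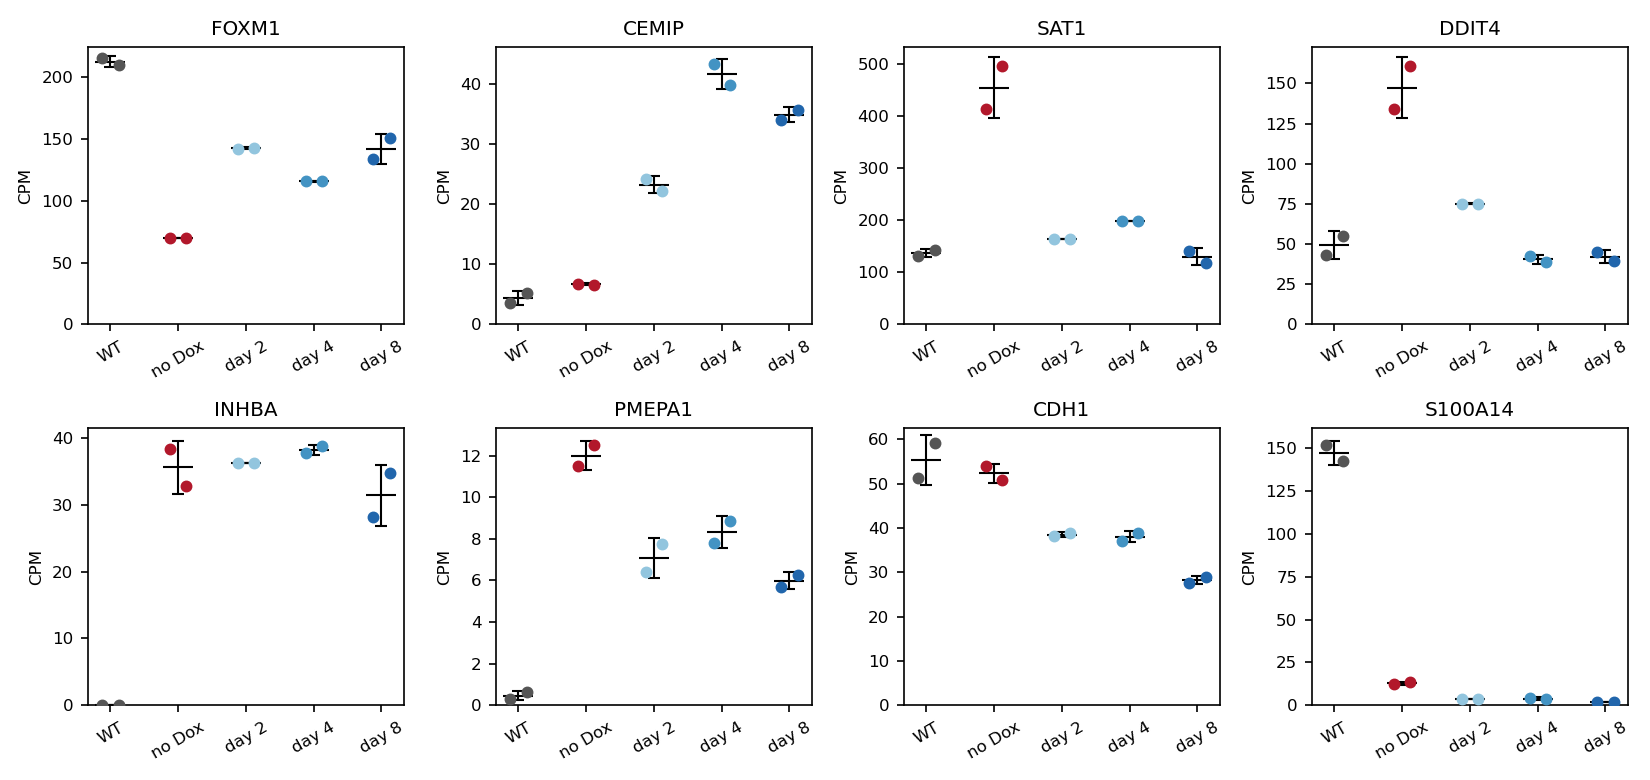
Abundance (CPM, 1 point per library in the 5 groups) of FOXM1, CEMIP, SAT1, DDIT4, INHBA, PMEPA1, CDH1 and S100A14. SAT1 fell from 454 CPM in uninduced cells to between 130 and 198 CPM with doxycycline (group means), near the WT mean of 137 CPM, while S100A14 moved further from its WT mean of 147 CPM.

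On all 3 days 396 genes were called higher and 208 lower, where independent overlap would give 3.38 and 1.4. Part of this excess may come from the uninduced libraries that all 3 comparisons share. In 20 simulations of unchanged groups with shared uninduced libraries the overlap was at most 0. Those simulations drew each gene independently and called at most 0, 0 and 19 genes at day 2, 4 and 8. An overlap of 0 was thus fixed in advance and does not test the excess. A joint test of the 3 days called 1878 genes; it called 878 and 873 without day 2 replicate 1 and 2, 968 and 1024 without day 4 replicate 1 and 2, 2961 without uninduced replicate 2, and 1179 with a weight per group. The 8 genes highest on average were KMT2D, CEMIP, FOXM1, the linker histone H1-2, KBTBD8, the checkpoint protein CLSPN, the glycerol-phosphate dehydrogenase GPD1 and SKA3, a kinetochore protein. Among these, KMT2D can hold reads of the induced domain itself. SKA3 rose by 0.85, 0.74 and 0.98 and kept its calls without any one library. At day 4, CLSPN and H1-2 lost theirs without uninduced replicate 2 (adjusted p = 0.057 and 0.08), day 4 replicate 1 (0.15 and 0.15) or day 4 replicate 2 (0.16 and 0.19), and KBTBD8 did so too (0.053, 0.22 and 0.25). KBTBD8 also lost its day 2 call without day 2 replicate 2 (adjusted p = 0.065), and GPD1 lost its day 2 call without either day 2 library (0.11 and 0.1) and its day 4 call without day 4 replicate 1 (0.1). The 8 lowest were S100A14, ARRDC4, ANGPTL4, DDIT4, CHAC1, SAT1, ANKRD37 and the transporter ABCC3. ARRDC4, an arrestin that responds to glucose, fell by 1.99, 1.21 and 1.81 on the log2 scale, ABCC3 by 1.51, 0.85 and 1.68, and CHAC1 by 1.29, 1.66 and 1.63. At day 2, ANGPTL4 lost its call without day 2 replicate 1 (adjusted p = 0.28) or replicate 2 (0.15), and ANKRD37 did so without uninduced replicate 2 (0.22), day 2 replicate 1 (0.21) or day 2 replicate 2 (0.17). ANKRD37 also lost its day 4 call without day 4 replicate 1 (adjusted p = 0.098) or replicate 2 (0.1).

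Cell cycle lists rose with doxycycline. G1/S genes were higher in 33, 27 and 35 of 36 cases at day 2, 4 and 8 and lower in 0 (36, 35 and 36 adjusted over the list alone), with medians of 0.5, 0.45 and 0.57 (adjusted p = 1.1e-35, 4.1e-37 and 1.4e-34, and adjusted p = 0.051 on each day with an estimated correlation). G2/M genes were higher in 27, 17 and 34 of 36 cases, and 1 was lower at day 8 (34, 27 and 34 higher and 0, 1 and 1 lower adjusted over the list alone). Their medians were 0.51, 0.34 and 0.61 (adjusted p = 4.3e-34, 5.3e-17 and 1.3e-31, and adjusted p = 0.051, 0.11 and 0.053 with an estimated correlation). RRM2 went from 212 ± 10.1 to 352 ± 3.08 CPM at day 2 and 379 ± 4.12 CPM at day 8, the helicase subunit MCM4 rose by 0.73 and 0.79, and CDC20, an activator of the anaphase complex, rose by 0.83 and 0.95. Both lists stayed below WT at day 8, with 32 G1/S genes and 26 G2/M genes called lower and medians of -0.68 and -0.41. The mitochondrial ribosome list rose, with 3, 0 and 12 of 40 genes higher (3, 0 and 16 adjusted over the list alone), such as MRPL19 at day 8 (0.54), and medians of 0.11, 0.15 and 0.24 (adjusted p = 0.0083, 0.0016 and 2.8e-06, and adjusted p = 0.78, 0.7 and 0.52 with an estimated correlation). Its calls at day 2 and day 4 ended without uninduced replicate 1 (-0.01, a change of sign, and 0.01; adjusted p = 0.83 and 0.72).

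The integrated stress response list, which covers targets of ATF4, fell on all 3 days. Lower genes numbered 16, 23 and 21 of 40 and higher ones 2, 1 and 2 (19, 29 and 24 lower and 2, 1 and 2 higher adjusted over the list alone). The medians were -0.24, -0.39 and -0.33 (adjusted p = 2.3e-09, 3.3e-36 and 3.3e-13, and adjusted p = 0.33, 0.078 and 0.23 with an estimated correlation). ASNS, which makes asparagine, was 125 ± 5.1 CPM at day 4 against 343 ± 16.9 CPM (-1.46, SE 0.07, adjusted p = 1.3e-06), and PCK2, a mitochondrial enzyme of phosphoenolpyruvate synthesis, fell by 0.99 at day 2 and 1.27 at day 8. Hypoxia and glycolysis genes were higher in 5, 1 and 3 of 40 cases and lower in 8, 15 and 19 (11, 2 and 3 higher and 12, 18 and 20 lower adjusted over the list alone). Their medians were -0.05, -0.22 and -0.37 (adjusted p = 0.31, 1.2e-12 and 2.8e-11, and adjusted p = 0.3 at day 4 and 0.33 at day 8 with an estimated correlation). ANGPTL4, a lipase inhibitor induced by hypoxia, fell by 1.99 at day 4 and 2.25 at day 8, and CA9, a carbonic anhydrase, went from 3.86 ± 1.98 to 0.262 ± 0.0639 CPM at day 8 (-3.94, SE 0.5, adjusted p = 0.00043; -3.26 without uninduced replicate 2). Mitochondrial DNA genes were higher in 2, 0 and 0 of 13 cases and lower in 1, 5 and 8 (3, 0 and 0 higher and 1, 11 and 9 lower adjusted over the list alone). Medians of that list were 0.04, -0.55 and -0.64 (adjusted p = 0.58, 4.7e-09 and 3.6e-07, and adjusted p = 0.37 at day 4 and 0.4 at day 8 with an estimated correlation). MT-CYB, a subunit of respiratory complex III, went from 3070 ± 216 to 1470 ± 220 CPM at day 8 (-1.06). Mitochondrial rRNA went from 2.8% and 1.27% of counts to 0.653% and 0.586% at day 8. The rRNA share was already down at day 2 (0.857% and 0.891%), when the list median was 0.04, so the 2 did not fall together.

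As a list, epithelial adhesion and keratin genes, lower in the knockout, fell further. Lower genes numbered 7, 5 and 19 of 33 and higher ones 0, 0 and 2 (9, 8 and 19 lower and 0, 0 and 2 higher adjusted over the list alone). The medians were -0.18, -0.14 and -0.33 (adjusted p = 0.0041, 0.0013 and 8.4e-06, and adjusted p = 0.25, 0.18 and 0.11 with an estimated correlation). CDH1, the E-cadherin gene, went from 52.3 ± 2.16 to 28.2 ± 0.878 CPM at day 8 (-0.89, SE 0.09, adjusted p = 0.00011), with 55.2 ± 5.63 CPM in WT. ELF3 fell by 1.86 and the junction protein gene TJP3 by 0.88. TJP3 was not lower in the knockout, at 19.6 ± 1.27 CPM in uninduced cells against 15.2 ± 0.983 CPM in WT. VIM rose by 0.91. The mesenchymal list that holds VIM did not pass at day 8, with 2 of 17 genes higher and 4 lower, S100A4 among the lower (median 0.08, adjusted p = 0.99; 2 and 4 adjusted over the list alone). Without uninduced replicate 2 the calls of the epithelial list at day 2 and day 4 ended (-0.18 and -0.17, adjusted p = 0.058 in each). Collagen and matrix genes were lower in 9, 3 and 11 of 25 cases and higher in 1 on each day (12, 4 and 11 lower and 2, 1 and 2 higher adjusted over the list alone). Their medians were -0.31, -0.08 and -0.39 (adjusted p = 3.3e-05, 0.0085 and 1.6e-07, and adjusted p = 0.18, 0.38 and 0.11 with an estimated correlation). LAMB3, a laminin subunit of the epithelial basement membrane, fell by 1.57 at day 8. Unlike its list, LAMB3 was already lower in the knockout and moved further from WT. Its means were 41.8 ± 3.71 CPM in WT, 19.1 ± 0.0894 CPM in uninduced cells and 6.41 ± 0.122 CPM at day 8. The day 4 call of that list ended without uninduced replicate 1 (-0.05, adjusted p = 0.18) or day 4 replicate 2 (-0.07, adjusted p = 0.11).

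TGF-beta and BMP targets, higher in the knockout, were lower in 9, 1 and 6 of 19 cases and higher in 0, 1 and 1 (11, 2 and 8 lower and 0, 1 and 1 higher adjusted over the list alone). The medians were -0.46, -0.07 and -0.42 (adjusted p = 2.3e-07, 0.28 and 0.00055, and adjusted p = 0.051 at day 2 and 0.11 at day 8 with an estimated correlation). PMEPA1 was 5.98 ± 0.405 CPM at day 8 (-1, SE 0.14, adjusted p = 0.00074), and INHBA was 31.4 ± 4.56 CPM (-0.17, adjusted p = 0.32). AP-1 and immediate early genes were lower in 6 of 25 cases at day 2 and 11 at day 8, and 1 was higher on each (6 and 14 lower adjusted over the list alone). The medians were -0.13 and -0.29 (adjusted p = 0.016 and 8.4e-06, and adjusted p = 0.62 and 0.4 with an estimated correlation), and JUNB fell by 0.77 at day 8. The day 2 call ended without uninduced replicate 2 (-0.03, adjusted p = 0.49). ERK pathway targets were lower in 8 of 23 cases and higher in 2 at day 8, also adjusted over the list alone, among them DUSP6 at 455 ± 11.6 CPM (-0.78; list median -0.13, adjusted p = 0.01, and adjusted p = 0.4 with an estimated correlation).

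Of the other lists, cholesterol synthesis rose at day 2, with 13 of 26 genes higher and 0 lower (19 and 0 adjusted over the list alone). The list median was 0.28 (adjusted p = 5.2e-10, and adjusted p = 0.12 with an estimated correlation). At day 4 the median was 0.09 (adjusted p = 0.025, and adjusted p = 0.49 with an estimated correlation), a call that ended without uninduced replicate 1 (0.07, adjusted p = 0.3), and at day 8 it was 0.03 (adjusted p = 0.33). p53 targets rose at day 8, with 9 of 32 higher and 2 lower (12 and 2 adjusted over the list alone), among them PLK2, a stress kinase (1.01), and MDM2, the p53 ligase (0.59). The median was 0.16 (adjusted p = 0.009, and adjusted p = 0.4 with an estimated correlation), and the call ended without uninduced replicate 1 (0.14, adjusted p = 0.088). MLL3-4 and COMPASS subunits were higher in 3, 2 and 7 of 19 cases (3, 3 and 8 higher and 0, 0 and 1 lower adjusted over the list alone). KMT2D on each day and the cofactor HCFC1 at day 8 (0.46) were among them. KMT2D counts can hold reads of the induced domain, and the list was not tested without KMT2D. The medians were 0.11, 0.09 and 0.17 (adjusted p = 0.0014, 0.0034 and 0.0035, and adjusted p = 0.31, 0.33 and 0.33 with an estimated correlation), and the day 4 call ended without uninduced replicate 2 (0.06, adjusted p = 0.052). Unfolded protein response genes were higher in 3, 4 and 7 of 24 cases and 1 was lower at day 8 (5, 11 and 8 higher and 0, 2 and 1 lower adjusted over the list alone). The chaperone gene HYOU1 rose by 0.4 at day 8, and list medians were 0.12, 0.2 and 0.21 (adjusted p = 0.045, 0.0029 and 0.008, and adjusted p = 0.47, 0.37 and 0.4 with an estimated correlation). The day 2 call ended without uninduced replicate 1 (0.08, adjusted p = 0.2) or day 2 replicate 2 (0.14, adjusted p = 0.082), and the day 8 call without uninduced replicate 1 (0.15, adjusted p = 0.052).

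Antigen presentation genes were lower in 7 of 23 cases and higher in 0 at day 2 (12 and 1 adjusted over the list alone; median -0.42, adjusted p = 0.00077, and adjusted p = 0.4 with an estimated correlation), a call that ended without uninduced replicate 2 (-0.24, adjusted p = 0.066). Interferon-stimulated genes were higher in 3 of 34 cases at day 4 (5 adjusted over the list alone; median 0.2, adjusted p = 0.015, and adjusted p = 0.18 with an estimated correlation), and the antiviral gene OAS3 rose by 0.59, a call that ended without day 4 replicate 1 or 2 (adjusted p = 0.067 and 0.076). Cytosolic ribosomal protein genes were lower in 13, 0 and 1 of 54 cases (39, 0 and 0 adjusted over the list alone), with medians of -0.41, -0.22 and -0.18 (adjusted p = 2.7e-11, 8.4e-06 and 0.015, and adjusted p = 0.54, 0.74 and 0.86 with an estimated correlation). Many have near-identical pseudogenes, and their share of counts was 6.1% and 7.87% in the uninduced libraries. Without uninduced replicate 2 the call ended and the median changed sign at day 4 (0.01, adjusted p = 0.99) and day 8 (0.04, adjusted p = 0.61), and the call ended at day 8 without day 8 replicate 2 (-0.03, adjusted p = 0.93). On the days for which no value is given, lists long enough for the camera test did not pass it with doxycycline. Among those, the signs of median, mean and test differed for retinoic acid, p53, NRF2 and Wnt genes at day 2, lipid and histone genes at day 4, and PRC1, HOX, Wnt, mesenchymal, NRF2 and histone genes at day 8.

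**Figure D4:**
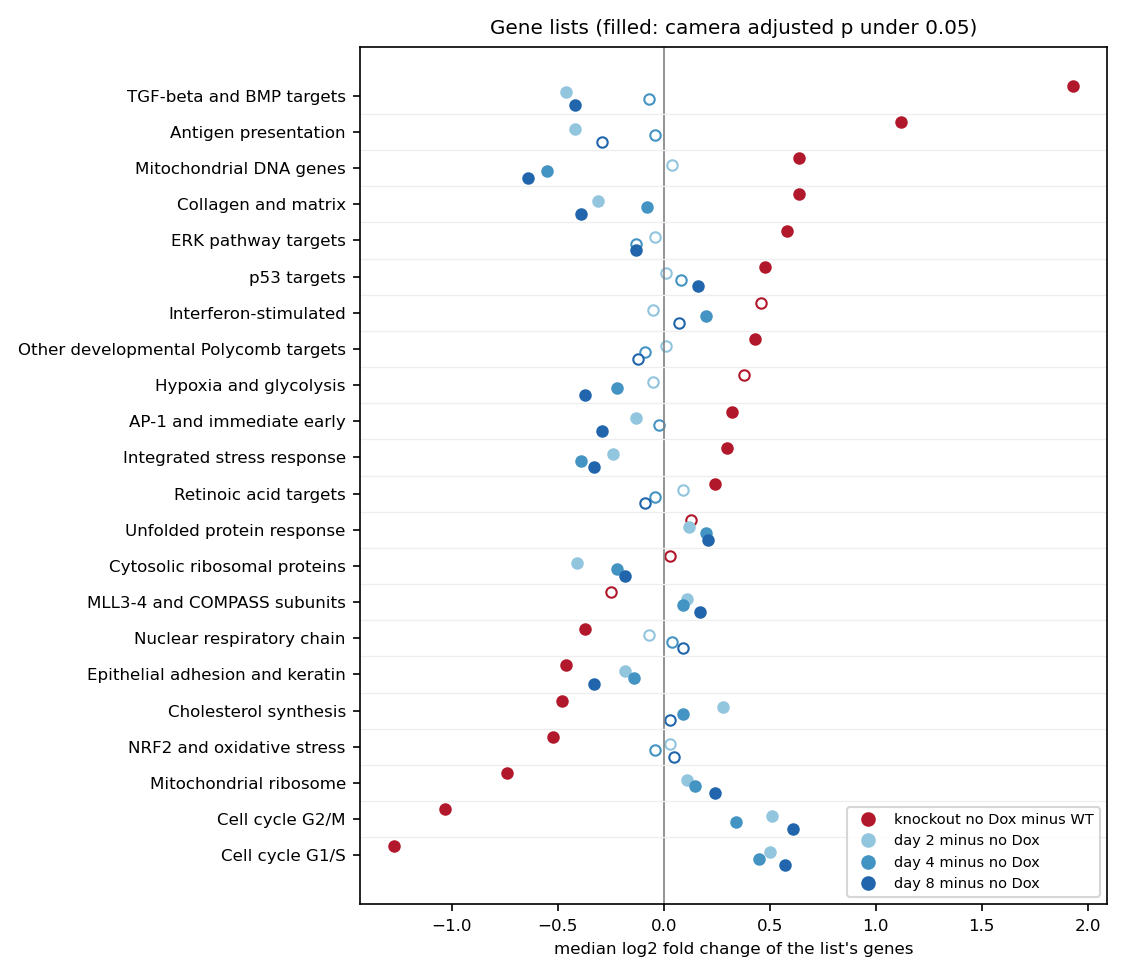
Median log2 fold change of 22 gene lists in 4 comparisons (knockout against WT, and day 2, 4 and 8 against uninduced), with filled points where camera with the preset correlation gave an adjusted p below 0.05. The G1/S list lay at -1.27 in the knockout and at 0.5, 0.45 and 0.57 with doxycycline.

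At day 2, 1929 genes were called against uninduced cells, 1077 higher and 852 lower, 14 and 182 of them by at least 1 on the log2 scale. Beyond the genes named above for all days, the strongest included ERCC6L, a helicase of mitotic chromosomes (0.95), and SSTR5-AS1, an antisense RNA (-1.78). The strand of the libraries is not given in the sources used here. The mitochondrial gene MT-ND6 (1.2, adjusted p = 0.049) lost its call without any of the 4 libraries (adjusted p = 0.1 without uninduced replicate 1, 0.26 without uninduced replicate 2, 0.18 and 0.21 without day 2 replicate 1 and 2). MALAT1 (-1.74) lost it without uninduced replicate 1 (-1.05, adjusted p = 0.082) or day 2 replicate 1 (0.12), and ANKRD30BL (-4.17, and -3.47 without uninduced replicate 1) without day 2 replicate 1 or 2 (0.078 and 0.1). TVP23C (-1.38), which has a near-identical copy, lost it without uninduced replicate 1 (-0.63) or day 2 replicate 1 (0.12 each) or day 2 replicate 2 (0.19). MALAT1 and ANKRD30BL were also highest in the uninduced library richest in mitochondrial rRNA, at 2683 and 18.13 CPM against 1203 and 7.843 CPM in the other. The count was 253 without day 2 replicate 2, 286 without day 2 replicate 1 and 393 with only the 4 libraries compared. Simulated changes of 1.5-fold, 2-fold and 4-fold were recovered in 43.3%, 65.7% and 92.4% of the genes so changed, rates that need not hold for the real data.

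At day 4, 779 genes were called, 490 higher and 289 lower, 13 and 41 of them by at least 1 on the log2 scale. SPTSSB, a subunit of the enzyme that starts sphingolipid synthesis (1.56), LOXL4, a matrix cross-linking oxidase (1.54), and TOE1, an RNA deadenylase (0.94), were among the strongest increases. ATOH8, SUSD2 and GPD1 (1.19, 1.07 and 1) lost their calls without day 4 replicate 1 (adjusted p = 0.088, 0.13 and 0.1), and SUSD2 also without day 4 replicate 2 (0.052). CSTA (-1.31) and ZBTB20 (-1.23) lost theirs without day 4 replicate 1 (0.16 and 0.22) or replicate 2 (0.17 and 0.18), and ZBTB20 also without uninduced replicate 1 (0.06). The count was 47 without day 4 replicate 1, 63 without day 4 replicate 2, 2033 without uninduced replicate 2 and 24 with only the 4 libraries compared. Simulated changes of 1.5-fold, 2-fold and 4-fold were recovered in 37.3%, 71.6% and 90.9% of the genes so changed, rates that need not hold for the real data.

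At day 8, 3321 genes were called, 1762 higher and 1559 lower, 21 and 339 of them by at least 1 on the log2 scale. SUSD2 (1.28), NMU, a neuropeptide (1.09), and NRP1, a co-receptor of VEGF and semaphorins (1.09), joined CEMIP, H1-2 (1.52) and FOXM1 among the strongest increases, and LAMB3, CA9 and ANGPTL4 are examples of strong decreases. MALAT1 (-2.56, and -1.87 without uninduced replicate 1) lost its call without day 8 replicate 1 or 2 (adjusted p = 0.056 and 0.068). With limma voom and a weight per group, chosen after the data were seen, 1324 genes were called, all of them among the 3321. The uninduced and day 8 replicates differed more than others (biological coefficient of variation 14.2% and 11.5%, against 4.52%, 2.25% and 3.16% in WT, day 2 and day 4). Without day 8 replicate 2 the count was 2102, and with only the 4 libraries compared it was 410. Simulated changes of 1.5-fold, 2-fold and 4-fold were recovered in 55.2%, 79.1% and 98.5% of the genes so changed, rates that need not hold for the real data. False calls numbered 145, against 14, 9 and 5 in the 3 comparisons above. Beside the 200 genes changed in that simulation, 145 false calls are more than an adjusted p below 0.05 allows. The 3321 calls, and the calls toward WT at day 8 given below, may therefore hold more false ones than the threshold states.

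Between day 8 and day 2, 5 genes were higher and 30 lower (35 in all, edgeR). Genes induced by hypoxia fell: BNIP3, a mitophagy receptor (-0.69), ALDOC, a glycolytic aldolase (-0.86), PFKFB4 (-0.83) and ANGPTL4 (-1.61). HAS3, already reduced in the knockout, fell by 0.76 and EGR1, an immediate early factor, by 0.65. The 5 higher genes, named after their values were seen as were BNIP3, ALDOC, PFKFB4 and HAS3, were PLK2 (0.86), NRP1 (0.66), RGS5 (0.92), ZBED2 (0.72) and WNT16 (0.54). In the hypoxia and glycolysis list 9 of 40 genes were lower and 0 higher (21 and 0 adjusted over the list alone; median -0.23, adjusted p = 7.9e-31 by camera, a test added after the data were seen, and adjusted p = 0.087 with an estimated correlation). The count was 2 without day 2 replicate 1, 2 without day 2 replicate 2, 22 without day 8 replicate 1 and 2 with only the 4 libraries compared. DESeq2 called 114 genes.

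Most genes changed in the knockout were not called with doxycycline. Those that were called moved mostly toward their WT level. Called away from WT were 74, 59 and 180 genes at day 2, 4 and 8. Called in the direction of WT were 1639 (17.3%), 657 (6.93%) and 2636 (27.8%) of the 9482 genes. At day 8 these were 1156 genes higher in the knockout that fell, such as SAT1, DDIT4 and ARRDC4, and 1480 lower in the knockout that rose, such as FOXM1, NMU and the methionine salvage gene ADI1 (0.98). Independent lists would share 460 and 487. A set of 20 simulations, added after the data were seen, kept WT at its own level and induced cells at the uninduced level. It gave at most 0, 0 and 20 genes toward WT. That set drew each gene independently and called at most 0, 0 and 38 genes against uninduced cells. A low count toward WT was therefore fixed in advance. Over all genes tested, which are not independent replicates, the covariance of the change with doxycycline and the difference of WT from uninduced cells was 0.227, 0.175 and 0.251, beside 0.0498, 0.05 and 0.0505 in simulations where all groups, WT included, had the uninduced level. The correlations were 0.5, 0.466 and 0.523, beside 0.585, 0.562 and 0.526 in those simulations, which hold noise alone, and 0.16, 0.155 and 0.142 where WT kept its own level. With a different uninduced library on each side the covariances averaged 0.167, 0.122 and 0.194, or 19.6%, 14.4% and 22.8% of the variance of the WT difference. Each side of that split holds 1 uninduced library, and part of the excess over simulation may come from the shared controls. With the weight per group 1141 genes moved toward WT at day 8, and with only the libraries compared 998.

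Of the 966 genes at least 1 lower on the log2 scale in the knockout, 431 (44.6%) were called toward WT at day 8 and 39 away. Of the 2412 at least 1 higher, 739 (30.6%) were called toward WT and 24 away. The few genes with the very strongest loss did not follow this pattern. Of the 12 named genes with the strongest increase in the knockout, 6 fell toward WT by day 8, among them PMEPA1, SATB1 (-0.5) and LRP1B (-0.96), and 0 rose further (edgeR). Of the 12 with the strongest decrease, KMT2D and H19 (1.08) rose. KMT2D counts can hold reads of the induced domain, so its rise does not test movement toward WT. In contrast, KRT7 (-1.83), ELF3 (-1.86), HAS3 (-0.74), S100A4 (-0.98) and S100A14 (-2.76) fell further from WT. KRT7 and ELF3 were low already, at 0.464 and 1.34 CPM in uninduced cells and 0.121 and 0.385 CPM at day 8, so few counts carry their decrease. S100A4 lost its day 8 call without uninduced replicate 2 (-0.88, adjusted p = 0.057). When genes were chosen with 1 uninduced library and measured with the other, those at least 2 lower on the log2 scale (73 and 77 genes) had a median movement toward WT of -0.18 and -0.11 at day 8. Those 1 to 2 lower moved toward WT by 0.23 and 0.43, and those at least 2 higher (509 and 408 genes) by 0.44 and 0.54.

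**Figure D5:**
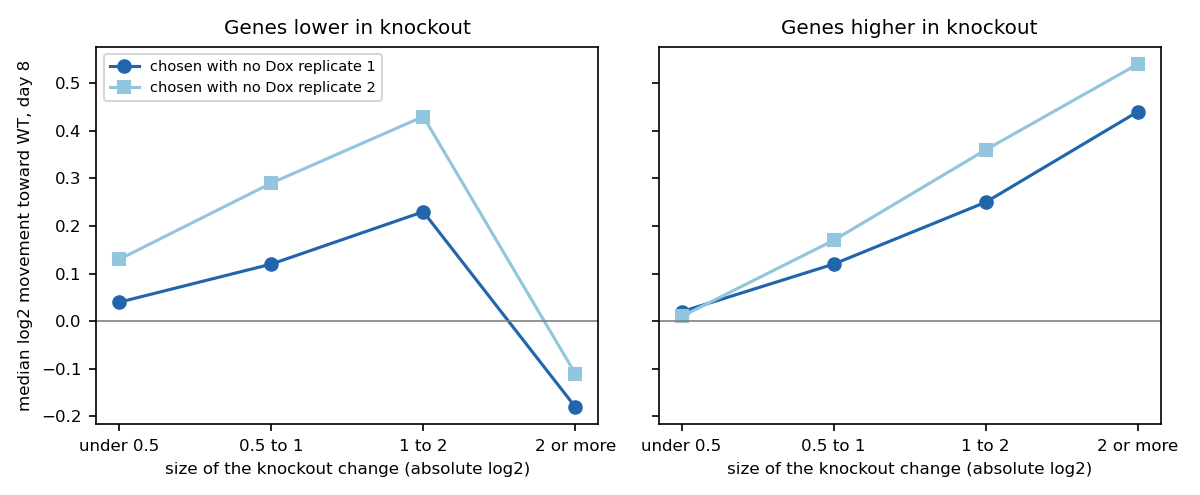
Median movement toward WT at day 8 (log2) by size of the knockout difference (log2), for genes lower and higher in the knockout, chosen with 1 uninduced library and measured with the other, 1 line per choice. Genes at least 2 lower lay at -0.18 and -0.11, and genes at least 2 higher at 0.44 and 0.54.

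At day 8, 7611 genes still differed from WT, 3867 higher and 3744 lower. KMT2D (-2.34, SE 0.14, adjusted p = 1.5e-07), the 2 cell cycle lists and the epithelial genes KRT7, ELF3 and S100A14 were among those that remained lower. Of the 9482 genes changed in the knockout, 6638 were called in the same direction at day 8. Another 26 were called in the opposite direction, and 2818 (29.7%) were not called. In simulated cells unchanged by doxycycline, 12.4% on average and 13% at most were not called, so a lost call alone does not show a return to WT. Beyond the 9482, 947 genes were newly called. The distance from WT was smaller at day 8 for 7783 of the 9482 (82.1%), with a median absolute log2 fold change of 0.55 against 0.77. Choosing genes by their knockout difference favours this. Simulated cells unchanged by doxycycline gave 57.5% on average and 58.4% at most over 20 simulations. Those simulations drew each gene independently and left out shifts shared by many genes of a library. Their narrow range therefore does not test whether such shifts make the excess. Without WT replicate 1 the count was 4430. Scaled by total counts alone, the median of all genes shifted by 0.151 on the log2 scale and the calls split into 5221 higher and 2648 lower.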

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

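The camera tests of day 8 against day 2 and all 7 tests of explanations below were chosen only after the results they concern were seen; the test of day 8 against day 2 for single genes was planned.

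The change with doxycycline differed between day 8 and day 2 in a direct test of the difference for 35 genes. Among genes named elsewhere, log2 differences of day 8 minus day 2 were -1.03 for S100A14, -1.61 for ANGPTL4, -0.84 for DDIT4, -2.93 for CA9, -0.69 for the sterol regulator INSIG1, -0.79 for MT-CYB and -0.65 for EGR1, and 0.66 for NRP1 and 0.86 for PLK2.

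The same difference passed camera with the preset correlation for 22 of 34 lists, 15 of which had passed on at least 1 day against uninduced cells. None passed with an estimated correlation, where adjusted p of the 15 ran from 0.087 to 0.4. The 15 are given here. Medians were lower at day 8 for epithelial adhesion and keratin (-0.09), collagen and matrix (-0.12), ERK pathway targets (-0.06), AP-1 and immediate early genes (-0.13), cholesterol synthesis (-0.25), hypoxia and glycolysis (-0.23), the integrated stress response (-0.05) and mitochondrial DNA genes (-0.69). Medians were higher for p53 targets (0.1), G1/S genes (0.08), G2/M genes (0.08), the mitochondrial ribosome (0.15), interferon-stimulated genes (0.14), antigen presentation (0.08) and cytosolic ribosomal proteins (0.22).

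Pattern 1 is the decrease of 1559 genes at day 8, such as SAT1, DDIT4 and LAMB3. Genes lower against uninduced replicate 1 alone, which holds the most mitochondrial rRNA, had a median of -0.69. Against replicate 2 their median was -0.47 (quartiles -0.76 to -0.21), with 88.8% below 0. Replicate 1 was thus not the sole source of the low values. The same day 8 libraries were used to choose and to measure these genes, which favours values below 0. Chance lows of the day 8 libraries are therefore not excluded. Whether the 1559 genes follow the rRNA content of the uninduced libraries stays open: their median log2 ratio of replicate 1 to replicate 2 was -0.02 (quartiles -0.17 to 0.2), but they were called with both libraries, which favours a ratio near 0. An effect of doxycycline itself stays open, and the induced domain is the biological candidate that the design names.

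Pattern 2 is the movement of knockout-changed genes toward WT. Chance values of the shared uninduced libraries do not account for all of it, since the covariance at day 8 with a different uninduced library on each side was 0.165 or more, above the bound of 0.05 set for this test. A state fixed in the uninduced cultures, which differ from the induced ones in more than doxycycline if handled apart, may add to it and cannot be told apart from an effect of the domain. The change from day 2 to day 8, which uses no uninduced library, had a covariance of 0.0266 with the difference of WT from uninduced cells, but single libraries gave 0.0115 to 0.0416, on both sides of the bound of 0.02. That the domain acts on part of the knockout-changed genes is a hypothesis that fits with this and was not tested apart.

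Pattern 3 is the rise of cell cycle genes with a fall of the integrated stress response. Doxycycline blocks mitochondrial translation, which is known to raise the integrated stress response; the list's medians of -0.24 or lower restate the pattern and so do not decide this, and mitochondrial DNA genes fell at day 4 and day 8 (-0.55 and -0.64). Uninduced replicate 1 alone did not make the change, as the lowest of 9 medians kept 85.5% of its value without that library. Effects of doxycycline, on mitochondrial translation or otherwise, or of culture conditions such as medium change or density cannot be told apart from the domain, because 0 WT libraries were given doxycycline. Faster division with the domain is therefore only a hypothesis.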

How the results depend on the processing

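The voom weight per group and the crossed block below were chosen after the data were seen; the other alternatives were planned. Of 495 results for named genes, 242 kept direction and call under every alternative run, 245 lost a call under at least 1 and 7 that had no call changed sign under at least 1. Named calls lost numbered 206 with only the libraries compared, 72 with voom weights, 61 with the replicate block, 71 without either day 2 library, 63 and 61 without day 4 replicate 1 and 2, 50 and 56 without uninduced replicate 1 and 2, 20 and 34 without day 8 replicate 1 and 2, 14 and 7 without WT replicate 1 and 2, and 5 to 9 under DESeq2, its size factors, total counts or the CPM filter. No call was lost without the filter (edgeR, 495 results). Of 58 list calls, 0 held with an estimated correlation, whose lowest adjusted p was 0.051, and fry kept 49. Depth limits WT most, at 5.19 M counts in replicate 2. The cause was not tested for any of these.

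With only the libraries compared, calls fell to 393 at day 2, 24 at day 4, 410 at day 8, 2 for day 8 against day 2, and 998 for genes moved toward WT. Requiring an absolute log2 fold change of 1 left 3378 for the knockout, 196, 54 and 360 for the 3 days, 6 for day 8 against day 2 and 1932 for day 8 against WT, by construction. Voom weights gave 1324 at day 8, 72 for day 8 against day 2, 1179 for the time course and 1141 toward WT. DESeq2 gave 114 for day 8 against day 2.

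No common pairing by number was seen. Correlations of deviations between equal numbers ran from -0.244 (uninduced and day 8) to 0.055 over 10 pairs of groups. Replicate 2 against 1 over all groups gave 0 called genes with edgeR, 236 at an unadjusted p below 0.05. A test of 1 effect over all groups cannot exclude pairing of some groups only or under crossed numbers. With replicate number as a block, counts were 9067 for the knockout, 1300, 429 and 2557 for the 3 days, 16 for day 8 against day 2, 7052 for day 8 against WT, 1202 for the time course, 2071 toward WT and 58 list calls. On the uninduced and day 8 libraries alone, the block as numbered gave 403 genes and the crossed block 5316.

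Leaving out 1 library at a time gave 6259 (WT replicate 1) to 9695 (uninduced replicate 2) for the knockout, 253 (day 2 replicate 2) to 2760 (uninduced replicate 1) at day 2, 47 (day 4 replicate 1) to 2033 (uninduced replicate 2) at day 4, 2102 (day 8 replicate 2) to 4176 (uninduced replicate 2) at day 8, 2 (day 2 replicate 1) to 32 (day 8 replicate 2) for day 8 against day 2, 4430 (WT replicate 1) to 7607 (day 8 replicate 1) for day 8 against WT, 873 (day 2 replicate 2) to 2961 (uninduced replicate 2) for the time course, 1809 (day 8 replicate 2) to 3491 (uninduced replicate 2) toward WT and 53 to 62 list calls.

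Medians of 3 called list results changed sign: cytosolic ribosomal proteins at day 8 (-0.41 to 0.04 over the libraries left out) and at day 4 (-0.22, and 0.01 without uninduced replicate 2), and the mitochondrial ribosome at day 2 (0.11, and -0.01 without uninduced replicate 1). The 7 single-gene results that changed sign did not pass with all libraries (adjusted p above 0.05): KMT2C at day 4 (-0.31 to 0.21), at day 8 (-0.49 to 0.03) and for day 8 against day 2 (0 to 0.2), and KDM6A at day 2 (-0.06 to 0.05), day 4 (-0.03 to 0.18), day 8 (-0.22 to 0.14) and day 8 against day 2 (-0.21 to 0.14). KDM6A at day 2 was also 0 with DESeq2 size factors, with DESeq2 and with only the libraries compared. The cause was not tested.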

Other observations

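The counts of list genes against WT at day 8 belong to a planned comparison; no test in this part was chosen after its result was seen.

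Some programmes stayed far from WT after 8 days of doxycycline. TGF-beta and BMP targets were higher than in WT in 15 of 19 cases and lower in 2, with a median of 1.34, and antigen presentation genes in 18 of 23 and lower in 1, with a median of 0.8. p53 targets were higher in 23 of 32 cases and lower in 2 (median 0.67), against 18 and 5 in uninduced cells (median 0.48). Epithelial adhesion and keratin genes were lower in 24 of 33 cases and higher in 3 (median -0.86), against 21 and 4 in uninduced cells (median -0.46). Mitochondrial ribosome genes were lower in 34 of 40 cases (median -0.5), and cholesterol synthesis genes in 17 of 26 (median -0.41). No set test was run on these differences from WT.

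The Polycomb lists PRC1 and PRC2 did not pass the camera test with doxycycline, but single members changed. BCOR, a subunit of a variant PRC1 complex, was 45.2 ± 0.408 CPM in WT, 141 ± 10.5 CPM in uninduced cells and 100 ± 3.36 CPM at day 8 (-0.49, adjusted p = 0.0012). PHF19, a PRC2 cofactor, was 85.9 ± 3.02, 33.4 ± 0.115 and 51.8 ± 2.77 CPM in the same groups (0.63, adjusted p = 0.00043). EZH1 and EZH2, alternative PRC2 methyltransferases, changed in opposite directions at day 8 (-0.44 and 0.32). The vitamin D hydroxylase CYP24A1 was 137 ± 6.82 CPM in WT, 54.2 ± 3.5 CPM in uninduced cells and 28 ± 0.0192 CPM at day 8 (-0.96, adjusted p = 5.7e-05), further from WT.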
